A study of Mus musculus with 9 samples.

How the data were processed

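Total RNA from the ears of 9 mice in 3 groups of 3 had been hybridised to Affymetrix Mouse Gene 1.0 ST arrays, per the labels. The authors deposited 1 table of expression values made with RMA, which corrects the background, normalizes by quantiles and summarises probes into probe sets, per the submitters' processing notes, whose version of RMA is not given in the sources used here. The deposited values are on a log2 scale, as judged from their range of 2.39 to 13.97, and this was not checked against scanner files, which were not used here. Whether all 9 arrays were normalized together is not given in the sources used here. Array medians were 6.08 to 6.10 for vehicle and 6.01 to 6.03 for the treated groups, and the values were not centred per gene. No genome build is named for the table, so no coordinates are given. No 2 arrays held the same values, and the smallest root mean square difference between any 2 was 0.129. The labels name the mice only through n = 3, and if the samples of a group were not separate animals, p-values measure only the spread between these samples.

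The table has 35556 rows. By the platform annotation 21789 rows carry 1 gene symbol, 1621 several and 12146 none, and 21698 of the named rows were found in a RefSeq gene table by Entrez identifier, which changed 0 symbols. Only rows with 1 symbol were tested. Where several probe sets carried the same symbol, which held for 999 genes, the probe set with the highest mean over the 9 arrays was kept, leaving 19938 genes, and no filter on dim genes was applied. Probe sets of a gene can disagree, and the mean over them was an alternative. IL-36 alpha appears under its annotated symbol Il1f6.

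Each gene was fitted with limma 3.58.1 in R 4.3.3, with a mean per group over all 9 arrays and no covariates, which leaves 6 residual degrees of freedom and, from the moderation of the variances, 3.16 prior degrees of freedom. Contrasts were anisomycin against vehicle, imiquimod against vehicle and anisomycin against imiquimod, each two-sided, with a moderated F test over the groups. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. A rank-based exact test of 3 against 3 could not go below p = 0.1, so calls rest on limma's pooled variances, and the number of arrays limits the precision.

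Of 826 memberships of 40 gene lists, fixed before the data were examined from general knowledge of skin inflammation, stress kinase signalling and the cell types of an ear, 748 were measured here. Lists were tested with limma's camera at its preset correlation of 0.01, adjusted over the 40 lists of a contrast, and again with an estimated correlation. Numbers of called members are given over all genes and adjusted over the list alone. The named genes follow a rule, also fixed before the data were examined. It takes the 8 largest rises and 8 largest falls per contrast among called genes whose groups do not overlap, leaving out predicted loci, clone names, immunoglobulin and T-cell receptor segments and small RNAs. It adds up to 4 called members per list by size of change, and 24 symbols in every case. Of those 24, 21 were measured, and Il22, Flg and Isg15 were not analysed here. Genes outside the rule are marked as chosen after their values were seen.

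The overlap of the treatments was set beside 100 simulations of 3 unchanged groups, drawn with each gene's moderated variance and compared with 1 shared control group, and beside the overlap of independent lists. On data simulated for the contrast of anisomycin with vehicle, with the means and spreads of the 19938 genes and 200 genes changed, the fit recovered 83.4% of genes changed by 0.5 on the log2 scale, 99.4% at 1 and 99.8% at 2, with 5.11% of calls false over 10 runs. A list of 20 genes shifted by 0.5 passed camera, at an unadjusted p under 0.05, in 10 of 10 runs and an unshifted list in 0. The simulated genes were drawn independently of each other. These runs therefore do not show how often calls are false among correlated genes or in lists of correlated members. They also changed few genes and gave each gene the same spread in all groups. In the data 45.6% of genes were called for this contrast, and median SDs were 0.098 for vehicle, 0.078 for anisomycin and 0.060 for imiquimod. Shares recovered and shares of false calls may therefore differ in the data.

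Alternatives chosen before the data were examined were a trended, robust variance prior, leaving out the dimmest 30% of genes, repeating the quantile normalization, centring arrays on their medians or on the 1000 genes of most stable rank, the mean of a gene's probe sets, testing all rows, array weights, the replicate number as a block, leaving out each array in turn, fitting only the 2 groups compared, and for lists an estimated correlation or limma's fry. Cyclic loess normalization was added after seeing the data.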

Results

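Whole-ear RNA was profiled in female C57BL/6 mice whose ears had been treated on 5 consecutive days with anisomycin or with imiquimod, beside a vehicle group. Anisomycin is an antibiotic that inhibits protein synthesis on ribosomes and activates stress kinases such as p38, and it was applied at 2 mg/ml in ethanol, 10 µl on each side of the ear. Imiquimod, a ligand of Toll-like receptor 7 whose cream is widely used to induce psoriasis-like dermatitis in mice, was applied as 10 mg of a 5% cream. The labels used here do not say which vehicle the controls received or for how many days, so ethanol, the cream base and the duration of treatment are not controlled separately here. Each group held 3 arrays, 9 in all, and 19938 genes were tested. Fold changes are differences of log2 expression values with n = 3 arrays per group, and SE is the standard error from limma.

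The largest component of variation set treated ears apart from vehicle ears. It carried 74.9% of the variance, and the next component, with 16.8%, set anisomycin apart from imiquimod. Correlations between arrays across genes, which are not independent replicates, were 0.993 to 0.997 within anisomycin, 0.997 to 0.998 within imiquimod and 0.993 to 0.996 within vehicle. Between groups they were 0.976 to 0.990 for anisomycin with imiquimod, 0.943 to 0.960 for imiquimod with vehicle and 0.927 to 0.951 for anisomycin with vehicle. The 3 anisomycin arrays were spread along the component that separates the treatments, with scores of -31.1, -19.4 and -9.48, while the imiquimod arrays lay between 22.6 and 24.4. The median SD of a gene between arrays of a group was 0.098 for vehicle, 0.078 for anisomycin and 0.060 for imiquimod on the log2 scale. By the moderated F test of limma, 10222 of the 19938 genes differed among the 3 groups.

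**Figure D1:**
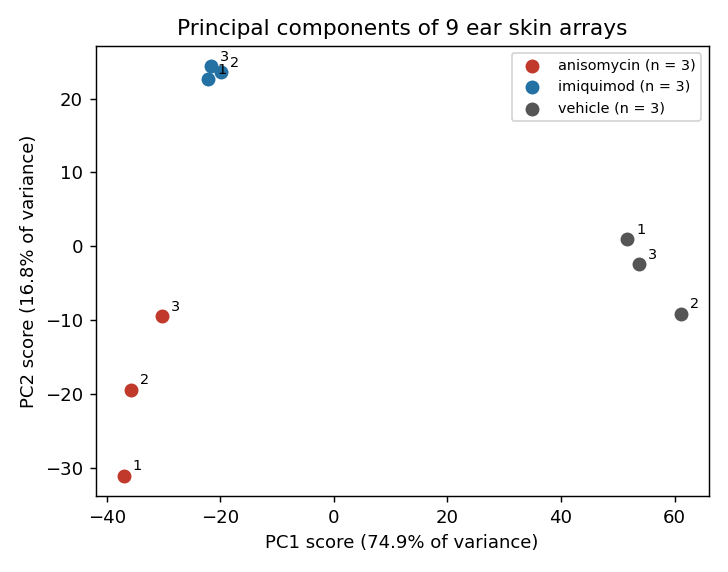
Scores of the 9 arrays on the first and second principal component of the log2 values (axes, with the percentage of variance), coloured by group and marked with the replicate number. Vehicle arrays lie at the right, from 51.7 to 61.1 on the first axis, and the treated arrays between -37.0 and -19.8.

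The next comparison sets ears treated with topical anisomycin against vehicle ears. Genes of the injured and regenerating epidermis rose most. Keratins 6b and 16, which hyperproliferating keratinocytes make, rose by 7.86 (Krt6b, SE 0.23) and 6.92 (Krt16, SE 0.10) on the log2 scale, the late cornified envelope gene Lce3e by 7.73 (SE 0.11), the growth factor epigen (Epgn) by 6.94 (SE 0.12) and the kallikrein Klk6 by 6.23 (SE 0.20). The beta-defensin Defb4 rose by 6.83 (SE 0.09), the cytokine Il1b by 6.63 (SE 0.19) and the chemokine Ccl3 by 6.23 (SE 0.24). Some of these genes were dim in vehicle ears. The vehicle means of Lce3e and Defb4 were 3.54 and 3.83, where the mean of the dimmest 1994 genes was 3.58, and signal over background was not tested. Rises from such levels may be understated, and the order of the largest rises is uncertain. The largest falls were changes of -4.45 for Krt24 (SE 0.49), -4.05 for Serpina3b (SE 0.31), -3.39 for Flg2 (SE 0.38), -3.16 for Alox12e (SE 0.44), -3.04 for Skint9 (SE 0.27), -3.03 for the metallothionein Mt4 (SE 0.31), -3.02 for the hair keratin-associated gene Krtap7-1 (SE 0.67) and -2.96 for Bbox1 (SE 0.29). As the naming rule requires, all 3 anisomycin arrays lay beyond all 3 vehicle arrays for each of these 16 genes, and each was called, with limma's adjusted p at most 0.00472.

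Among gene lists fixed before the data were examined, all 26 measured stress keratin and regenerative epidermis genes rose with anisomycin, with a median log2 fold change of 4.79. The list passed the camera test at an adjusted p of 1.01e-23, with adjusted p = 0.0569 with an estimated correlation. Members of this list in the Sprr2 and Lce3 families, like the Stfa genes named further on, are near-identical copies whose probe sets can share signal, so values of single members are uncertain. Antimicrobial genes moved up as well. Of 21 measured, 15 rose, 2 fell and 4 were not called, with rises of 5.85 for Saa3, 5.50 for S100a8 and 5.01 for S100a9 (camera adjusted p = 3.53e-08, and adjusted p = 0.0569 with an estimated correlation). Neutrophil markers gave 14 higher and 2 not called of 16, with Cxcr2 at 4.97 and Trem1 at 5.43 (adjusted p = 2.54e-10, and adjusted p = 0.102 with an estimated correlation). Of the 14 neutrophil chemoattractants and growth factors 13 rose, Cxcl2 by 5.96 and Cxcl5 by 4.90 (adjusted p = 4.2e-09, and adjusted p = 0.144 with an estimated correlation). Cxcr2 and Trem1 stand in both of these lists. Monocyte and macrophage markers rose in 18 of 21 cases, among them the integrin Itgam by 2.92 and Cd14 by 3.43 (adjusted p = 7.24e-09, and adjusted p = 0.102 with an estimated correlation). Of 21 monocyte and lymphocyte chemokines, 17 rose and 3 fell, with Ccl7 at 2.93 and Ccl2 at 2.75 (adjusted p = 1.8e-05, and adjusted p = 0.144 with an estimated correlation).

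The cytokine lists were uneven. In the IL-1 and IL-36 family 16 of 18 genes rose and 1 fell, with Il1a at 3.64 and the inflammasome gene Nlrp3 at 3.36 (adjusted p = 1.21e-06, and adjusted p = 0.238 with an estimated correlation). In the IL-17 and IL-23 axis 9 of 20 measured genes were called, a share near the 45.6% of all genes called in this contrast. All 9 were higher, led by Il24 at 5.13, Il6 at 3.28, Tnf at 1.94 and Il23a at 1.49 (adjusted p = 0.000314, and adjusted p = 0.229 with an estimated correlation). The cytokine genes Il17a and Il17f had log2 fold changes of 0.05 and 0.01 and were not called, nor were Il12b at -0.11 and Ccl20 at 0.73, though Ccl20 passed the threshold with array weights and some other alternatives. Of the 34 MAP kinase and immediate early genes, 25 rose and 2 fell, with Fosl1 at 3.52, Dusp5 at 2.47, Atf3 at 2.29 and the p38 phosphatase gene Dusp1 at 2.13 (adjusted p = 3.89e-09, and adjusted p = 0.144 with an estimated correlation). The p38 alpha gene itself, Mapk14, was at -0.06 and not called. All 27 ribosome biogenesis genes rose, with a median of 0.94 and Nop56 at 1.64 (adjusted p = 3.17e-15, and adjusted p = 0.144 with an estimated correlation). The integrated stress and unfolded protein response list gave 20 higher and 3 lower of 26, with the cystine transporter Slc7a11 at 4.17 and the chaperone Hspa5 at 1.49 (adjusted p = 2.56e-07, and adjusted p = 0.102 with an estimated correlation). Of 29 cell cycle genes 26 rose, with Plk1 at 2.04 (adjusted p = 3.89e-09, and adjusted p = 0.345 with an estimated correlation). In the TLR and NF-kB list 22 of 23 rose, with Clec4e at 5.11 and Clec4d at 4.73 (adjusted p = 7.02e-13, and adjusted p = 0.144 with an estimated correlation). Interferon-induced genes rose in 15 of 27 cases and fell in 1, with Oasl2 at 1.72 and Ifit1 at 1.31 (adjusted p = 0.00341, and adjusted p = 0.558 with an estimated correlation).

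Markers of muscle, fat, cartilage and fibroblasts fell, while the endothelial and lymphatic list, with 7 higher and 3 lower of 16, was not called (adjusted p = 0.0795), nor were the melanocyte (0.0538) and sebaceous gland (0.0888) lists. Hair follicle markers fell in 12 of 20 cases and rose in 2, with a median of -0.41 (adjusted p = 0.0204, and adjusted p = 0.4 with an estimated correlation). That call ended without vehicle replicate 3. All 18 skeletal muscle genes fell, with a median of -1.77, Pvalb at -2.68 and Myh4 at -2.52 (adjusted p = 4.12e-09, and adjusted p = 0.309 with an estimated correlation). Adipocyte markers fell in 12 of 14 cases, with Retn at -2.32 and Adipoq at -1.52 (adjusted p = 1.54e-06, and adjusted p = 0.272 with an estimated correlation). Cartilage markers fell in 13 of 16 cases and Sox9 rose, with Chad at -2.07 (adjusted p = 0.000314, and adjusted p = 0.287 with an estimated correlation), and of 16 fibroblast markers 11 fell and 2 rose, with Col1a1 at -1.49 and Dpt at -1.59 (adjusted p = 0.00075, and adjusted p = 0.238 with an estimated correlation). These shifts go with the gene groups above, in the same arrays. In the cornified envelope list 17 of 28 rose and 5 fell, with Rptn at 4.73 and loricrin (Lor) at -1.27 (adjusted p = 0.00284, and adjusted p = 0.558 with an estimated correlation).

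In total 9095 genes, 45.6% of those tested, were called for anisomycin against vehicle, 4454 higher and 4641 lower, of which 1016 rose and 687 fell at least 2-fold. The arrays of the 2 groups did not overlap for 51.3% of genes, where chance gives 10%. Adjusted over the list alone, the stress keratin, IL-17 and IL-23, and muscle lists gave 26, 9 and 18 called members, the same numbers as over all genes, while the MAP kinase list gave 29 in place of 27. Of the 21 measured genes named in advance whatever their values, 15 rose, 1 fell and 5 were not called, and the call of Tlr7 (0.31) ended without anisomycin replicate 2 or 3 or without vehicle replicate 2, at an adjusted p of up to 0.1. The share of called genes that were higher, 49%, became 61.5% with arrays centred on their medians and 37.1% with arrays centred on stable genes, so the balance of rises and falls depends on the scaling.

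Imiquimod was compared with vehicle in the same way. Stress keratins, calprotectin genes and Il1b led the rises. Krt6b rose by 7.71 (SE 0.23), Lce3e by 6.99 (SE 0.11), Krt16 by 6.67 (SE 0.10), the calprotectin genes S100a8 by 6.62 (SE 0.12) and S100a9 by 6.29 (SE 0.10), Stfa3 by 6.15 (SE 0.17), Sprr2e by 6.15 (SE 0.14) and Il1b by 6.097 (SE 0.19). As with anisomycin, rises from a dim vehicle level, such as those of Lce3e and of Stfa3 (vehicle mean 4.17), may be understated and their order is uncertain. The largest falls were those of Serpina3b at -3.62 (SE 0.31), Krt77 at -3.14 (SE 0.24), Krt24 at -3.11 (SE 0.49), Cyp2g1 at -2.84 (SE 0.56), Flg2 at -2.80 (SE 0.38), Paqr7 at -2.80 (SE 0.14), Bbox1 at -2.77 (SE 0.29) and the muscle gene Pvalb at -2.67 (SE 0.24).

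With imiquimod all 26 stress keratin genes rose, with a median of 4.90 (camera adjusted p = 1.4e-27, and adjusted p = 0.039 with an estimated correlation), and of 21 antimicrobial genes 16 rose and 1 fell, with Defb4 at 5.81 and Defb3 at 5.67 (adjusted p = 1.42e-10, and adjusted p = 0.0322 with an estimated correlation). These were the only lists whose call held with an estimated correlation, in this or any of the 3 comparisons. All 29 cell cycle genes rose, with a median of 1.61, Plk1 at 2.79, Rrm2 at 2.20 and Bub1 at 2.16 (adjusted p = 1.02e-16, and adjusted p = 0.203 with an estimated correlation). As with anisomycin, all 27 ribosome biogenesis genes rose, with a median of 0.87 (2.77e-15, and 0.132 with an estimated correlation). Of 34 MAP kinase and immediate early genes 25 rose and 3 fell (1.34e-06 and 0.199). Of 26 integrated stress and unfolded protein response genes 21 rose and 2 fell (2.37e-09 and 0.0819), and 20 of 23 TLR and NF-kB genes rose (1.89e-11 and 0.163). In the IL-17 and IL-23 axis 14 of 20 genes rose and none fell, with Ccl20 at 2.63, Il19 at 2.03, Zc3h12a at 1.96 and Il17f at 0.83 (adjusted p = 2.26e-07, and adjusted p = 0.12 with an estimated correlation), while Il17a was at 0.04 and not called. The IL-1 and IL-36 family gave 15 higher of 18, with IL-36 alpha (Il1f6) at 3.78 and Il1a at 3.43 (adjusted p = 1.56e-08, and adjusted p = 0.163 with an estimated correlation). Neutrophil markers rose in 13 of 16 cases, with Cxcr2 at 4.71 and Mmp8 at 1.92 (adjusted p = 5.04e-11, and adjusted p = 0.0819 with an estimated correlation). Interferon-induced genes rose in 15 of 27 cases, with Rtp4 at 1.77, Irf7 at 1.75 and Ifit1 at 1.45 (adjusted p = 2.52e-05, and adjusted p = 0.478 with an estimated correlation), and the receptor gene Tlr7 was at 0.16 and not called. Of 21 genes of cholesterol and fatty acid synthesis 12 rose and 2 fell, with Sqle at 1.23 and Idi1 at 1.22 (adjusted p = 0.00238, and adjusted p = 0.572 with an estimated correlation). This list's call ended after cyclic loess normalization, an alternative chosen after seeing the data. The eicosanoid list gave 8 higher and 3 lower of 18, with the lipoxygenase Alox8 at 4.89 and Ptgs2 at 4.30 (adjusted p = 0.00209, and adjusted p = 0.235 with an estimated correlation). In the circadian clock list 10 of 15 fell and 1 rose, with Hlf at -1.98 (adjusted p = 0.00251, and adjusted p = 0.212 with an estimated correlation). This list was similar with anisomycin, with 8 lower and 2 higher, though not called there (camera adjusted p = 0.0569). It was not called between the treatments either (camera adjusted p = 0.4). All 18 muscle genes fell, with a median of -1.80 (adjusted p = 1.11e-09, and adjusted p = 0.238 with an estimated correlation), and 12 of 14 adipocyte markers fell, with a median of -0.998 (adjusted p = 1.2e-05, and adjusted p = 0.24 with an estimated correlation). Cartilage markers fell in 13 of 16 cases, with a median of -0.69 (adjusted p = 2.63e-05, and adjusted p = 0.203 with an estimated correlation), and of 16 fibroblast markers 12 fell and 1 rose, with a median of -0.70 (adjusted p = 8.13e-05, and adjusted p = 0.163 with an estimated correlation).

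For imiquimod against vehicle 8519 genes, 42.7% of those tested, were called, 4062 higher and 4457 lower, with 850 up and 519 down at least 2-fold. Adjusted over the list alone, the counts of called members were 26 for stress keratins, 29 for cell cycle, 14 for the IL-17 and IL-23 axis and 15 in place of 14 for cholesterol and fatty acid synthesis. Of the 21 genes named in advance 17 rose and 4 were not called (Il17a, Il6 at 0.89, Lor at -0.36 and Tlr7). Some of those rises were small and near the threshold, and did not rest on 1 particular array. The calls of Il23a (0.52), Cxcl1 (0.82), Mapk14 (0.36) and Dusp1 (0.54) ended without any 1 of 5, 3, 4 and 7 arrays. The adjusted p then reached up to 0.0778, 0.0728, 0.0716 and 0.138. For Dusp1 these arrays included anisomycin replicates 1 and 2, which enter this contrast only through the variances. The share of called genes that were higher, 47.7%, became 58.1% with arrays centred on their medians and 36.4% with arrays centred on stable genes.

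**Figure D2:**
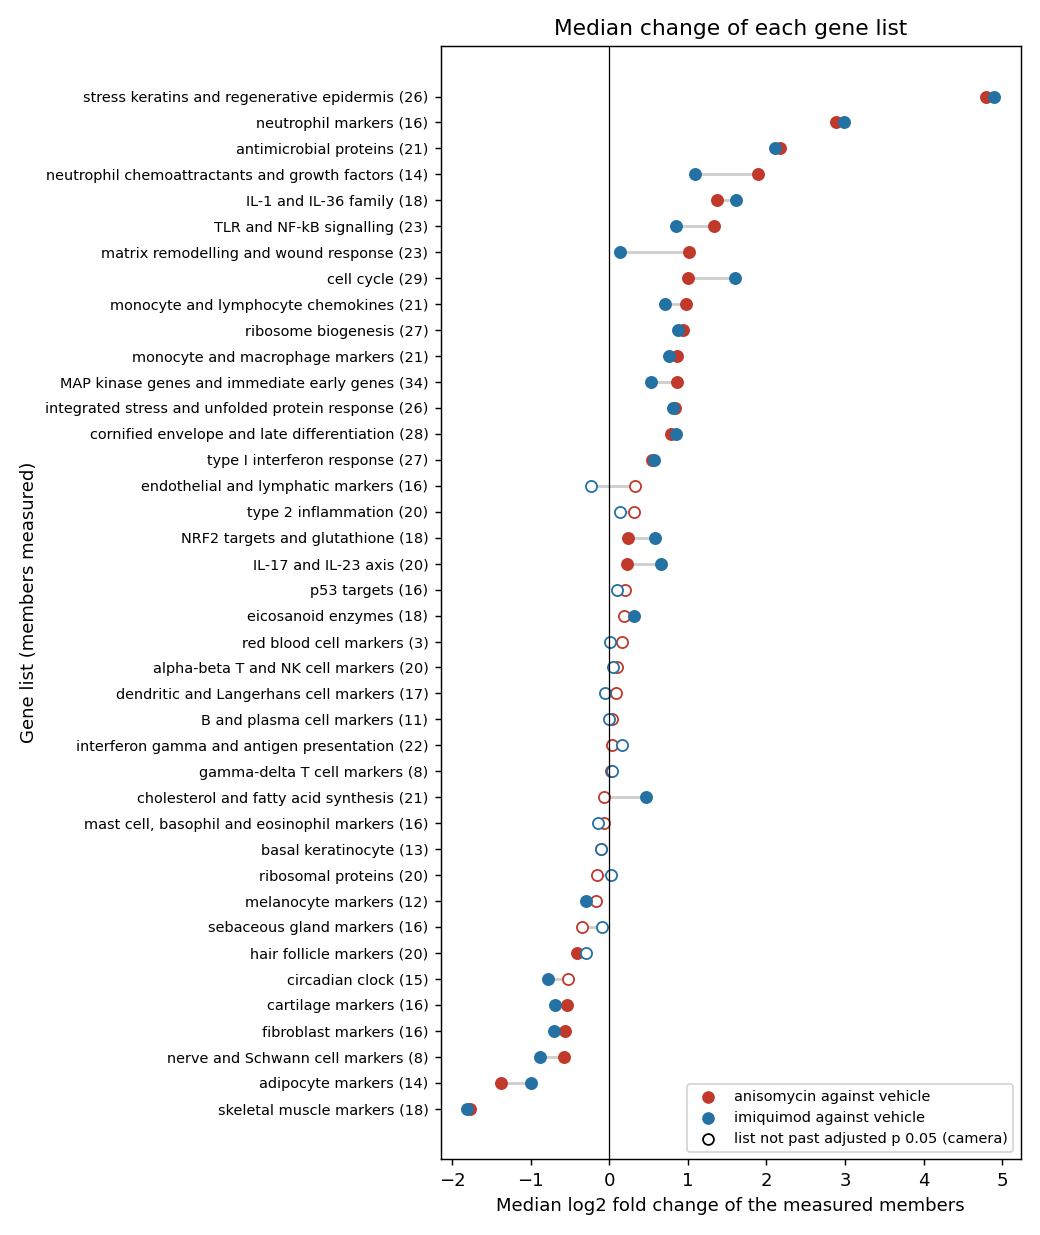
Median log2 fold change (horizontal axis) of the measured members of each of the 40 gene lists (vertical axis, members measured in parentheses) for anisomycin (red) and imiquimod (blue) against vehicle, each from 3 against 3 arrays. Filled points passed limma's camera test at an adjusted p under 0.05 with the preset correlation. Stress keratins lie at 4.79 and 4.90 and skeletal muscle genes at -1.77 and -1.80.

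The effects of the treatments were compared gene by gene. Krt6b, Lce3e, Krt16 and Il1b were among the 8 largest rises of both, and Krt24, Serpina3b, Flg2 and Bbox1 among the 8 largest falls of both. The log2 fold changes correlated across genes with a Pearson r of 0.866 and a Spearman rho of 0.808, and the sign was shared by 79.9% of genes. The treatments share their vehicle arrays, and a simulation of 3 unchanged groups, with the controls shared in the same way, gave a mean r of 0.499 and 66.7% shared signs. The covariance of the fold changes was 0.323, against 0.00432 in the simulation. Of the called genes 3195 rose in both, where independent lists of those sizes would share 907, and 3485 fell in both, where 1038 would be shared. That expectation takes no account of the shared controls. The simulation, which does, called a mean of 0.01 genes in both in the same direction, against 6680 observed, but its genes were all unchanged. Among changed genes part of the excess over independent lists may come from the shared controls, since 3 vehicle arrays cannot be divided into sets of at least 2.

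Differences between the treatments were tested directly, in the contrast of anisomycin with imiquimod. The vehicle arrays cancel in its fold changes but contribute to the variances of its tests. The genes furthest above imiquimod included proteases and signalling molecules. The receptor gene Gprc5a was higher by 4.76 (SE 0.17), the protease genes Tmprss11b by 4.48 (SE 0.10) and Mmp13 by 4.29 (SE 0.24), Ifi202b by 3.61 (SE 0.15), Il24 by 3.58 (SE 0.10), the activin gene Inhba by 3.58 (SE 0.23), Ppbp by 3.25 (SE 0.19) and the endothelin gene Edn1 by 3.24 (SE 0.14). On the other side the lipoxygenase Alox8 differed by -4.46 (SE 0.08), lactoperoxidase (Lpo) by -3.60 (SE 0.12), Sprr2b by -3.47 (SE 0.13), urate oxidase (Uox) by -3.34 (SE 0.07), Aox4 by -3.03 (SE 0.32), Defb3 by -2.67 (SE 0.10), Il1f6 by -2.58 (SE 0.25) and Defb6 by -2.48 (SE 0.30), all lower with anisomycin. The arrays of the 2 groups did not overlap for any of these 16 genes, as the naming rule requires. Differences from a dim level, such as that of Tmprss11b (imiquimod mean 4.30) or Uox (anisomycin mean 4.19), may be understated here too.

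**Figure D3:**
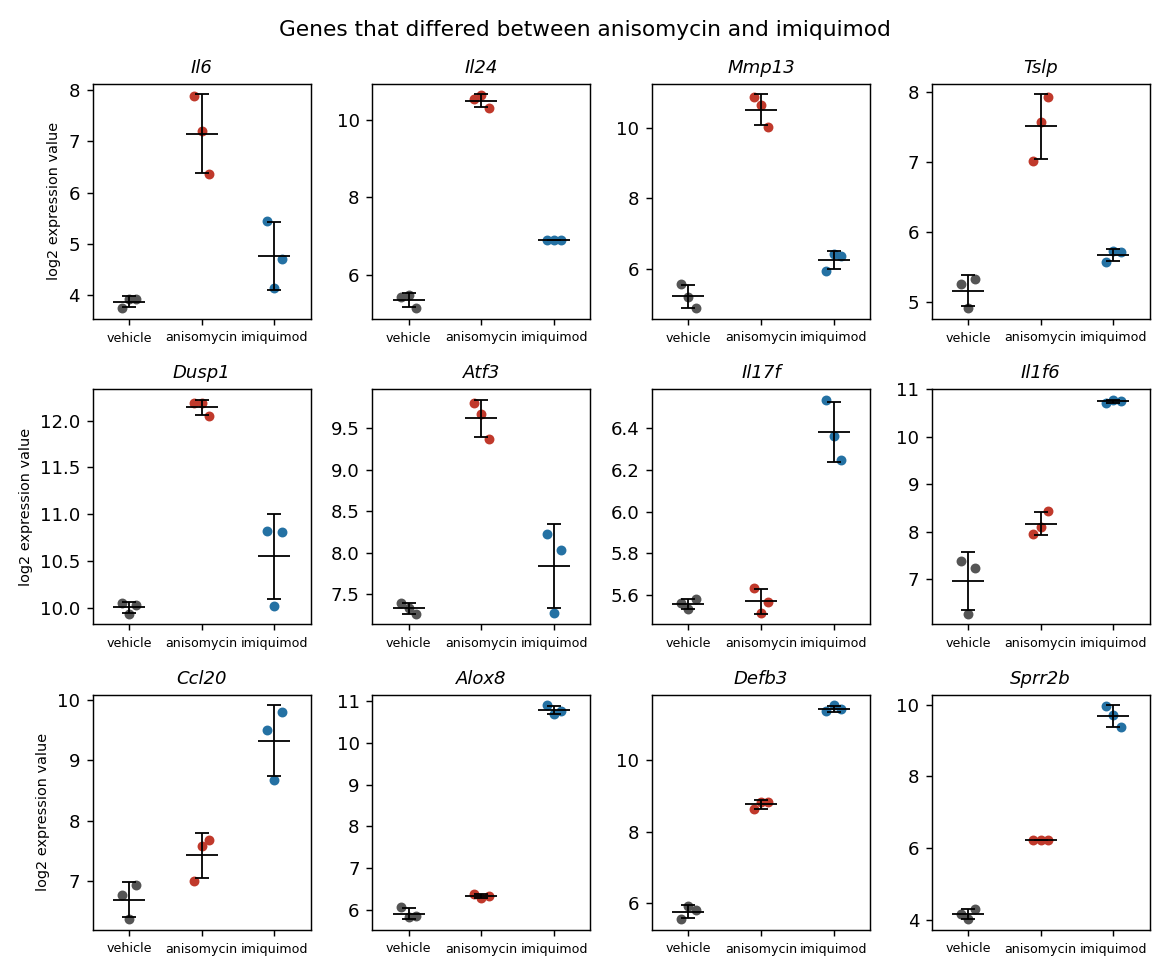
Log2 expression values (vertical axes, a separate scale in each panel) of 12 genes on each array of the vehicle, anisomycin and imiquimod groups (horizontal axes, points), with the group mean and SD (bars, n = 3). The anisomycin arrays lie above the imiquimod arrays for Il6, Il24, Mmp13, Tslp, Dusp1 and Atf3, and below them for Il17f, Il1f6, Ccl20, Alox8, Defb3 and Sprr2b.

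Single cytokine genes differed in both directions. Il6 was higher with anisomycin than with imiquimod by 2.39, Tslp by 1.83, Il33 by 1.31, Il23a by 0.97 and Tnf by 0.80, whereas Il17f (-0.81), Il12b (-0.63), Ccl20 (-1.90) and Cxcl13 (-1.25) were lower. Il17a differed by 0.02 and was not called. The IL-17 and IL-23 axis as a list had 5 higher and 9 lower of 20 and did not pass camera (adjusted p = 0.297), nor did the antimicrobial list, with 6 higher and 9 lower of 21 (adjusted p = 0.294). Within the antimicrobial list S100a8 (-1.13) and S100a9 (-1.28) were lower with anisomycin, while Defb14 (1.34) and Defb4 (1.01) were higher.

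Of the 40 lists 15 passed camera between the treatments. Cell cycle genes were lower with anisomycin in 23 of 29 cases, with a median of -0.63 and Bub1b at -0.93 (adjusted p = 3.92e-13, and adjusted p = 0.515 with an estimated correlation). Genes of cholesterol and fatty acid synthesis were lower in 16 of 21, with a median of -0.57 and Nsdhl at -0.80, Scd2 at -0.78 and Acaca at -0.78 (adjusted p = 8.39e-11, and adjusted p = 0.515 with an estimated correlation). Sebaceous gland markers had 4 lower and 2 higher of 16, with a median of -0.51 (adjusted p = 0.0126, and adjusted p = 0.55 with an estimated correlation), and adipocyte markers 2 lower of 14 and 12 not called, with a median of -0.27 (adjusted p = 0.0083, and adjusted p = 0.57 with an estimated correlation). The calls of those 2 genes, Car3 (-0.55) and Fabp4 (-0.51), each ended without any 1 of 6 of the arrays, at adjusted p of up to 0.124 and 0.128. Of 34 MAP kinase and immediate early genes 14 were higher and 3 lower with anisomycin, with Dusp10 at 1.86, Atf3 at 1.77, Gadd45b at 1.60 and Dusp1 at 1.59 (adjusted p = 1.7e-06, and adjusted p = 0.515 with an estimated correlation). Neutrophil chemoattractants were higher in 10 of 14, with Cxcl5 at 1.71 and Cxcl3 at 1.62 (adjusted p = 7.83e-07, and adjusted p = 0.515 with an estimated correlation), while the neutrophil markers themselves were divided, 6 higher and 7 lower of 16 (adjusted p = 0.194). Matrix remodelling genes were higher in 16 of 23 and lower in 3, with Timp1 at 1.17 and Adamts1 at 1.08 (adjusted p = 5.35e-06, and adjusted p = 0.515 with an estimated correlation). Endothelial and lymphatic markers were higher in 7 of 16, with Pdpn at 1.28, Icam1 at 1.12 and Cdh5 at 1.02 (adjusted p = 3.53e-06, and adjusted p = 0.531 with an estimated correlation), and TLR and NF-kB genes in 12 of 23, with 1 lower and Tnfaip3 at 1.24 (adjusted p = 0.000188, and adjusted p = 0.55 with an estimated correlation). Of 20 ribosomal protein genes 6 were lower, Rps9 at -0.42, and none higher (adjusted p = 0.000129, and adjusted p = 0.55 with an estimated correlation), while of 27 ribosome biogenesis genes 11 were higher and 1 lower, with Nop56 at 0.56 (adjusted p = 0.000915, and adjusted p = 0.55 with an estimated correlation). None of the 18 muscle genes was called, and their median difference was -0.004 (adjusted p = 0.803). For many of the called lists the anisomycin arrays differed among themselves in the same direction, and for some by about as much. The median of anisomycin replicate 1 minus replicate 3 was -0.60 for cell cycle genes, -0.53 for cholesterol and fatty acid synthesis, -0.51 for sebaceous gland, -0.25 for adipocyte and -0.12 for ribosomal protein genes, where the treatments' median differences were -0.63, -0.57, -0.51, -0.27 and -0.15. It was 0.49 for neutrophil chemoattractants, 0.31 for matrix remodelling, 0.26 for TLR and NF-kB, 0.25 for endothelial and lymphatic and 0.165 for MAP kinase and immediate early genes, where the treatments' were 0.68, 0.55, 0.44, 0.41 and 0.35, and it was 0 for ribosome biogenesis, where the treatments' was 0.20.

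Between anisomycin and imiquimod 4059 genes, 20.4% of those tested, were called, 2147 higher and 1912 lower with anisomycin, of which 184 and 140 differed at least 2-fold. The count moved to 2589 without anisomycin replicate 1, 2548 without anisomycin replicate 2, to 2523, 2547 and 2563 without imiquimod replicates 1, 2 and 3, to 4766 without vehicle replicate 2, and to 8557 with array weights. Adjusted over the list alone, 27 cell cycle, 19 cholesterol and fatty acid and 22 MAP kinase genes were called, against 23, 16 and 17 over all genes. Of the 21 genes named in advance 7 were higher, 8 lower and 6 not called, and the calls of Cxcl2 (0.97), Krt6a (0.44), Lor (-0.91) and Mapk14 (-0.42) each ended without some single arrays, for Lor vehicle replicate 3 among them, at adjusted p of up to 0.098, 0.088, 0.0996 and 0.0792.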

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

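Of the tests in this part, that of a brightness trend behind the spread of the anisomycin arrays was chosen after its result had been seen. Cyclic loess normalization was added after seeing the data, though its test on the muscle genes was set out before that test's result was seen, and the patterns themselves were noticed in the data they were tested on.

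Some genes went in opposite directions. There were 116 genes called in opposite directions against vehicle and called different between the treatments, 73 of them higher with anisomycin and 43 higher with imiquimod. Such genes were rare, since independent lists of those sizes would share 996 and 946, an expectation that takes no account of the shared controls. The condition of a called difference removed none of the genes called in opposite directions. The p38 and JNK phosphatase gene Dusp10 changed by 0.85 with anisomycin and -1.01 with imiquimod, a difference of 1.86, and the transcription factor gene Sox9 by 0.96 and -0.72, a difference of 1.68. Chosen after their values were seen, the collagen receptor gene Itga2 (1.83 and -0.57), the small heat shock protein gene Hspb1 (0.92 and -0.73) and the lipase gene Lipk (-0.98 and 1.03) belong to this set. Rows of the array outside the comparisons, those without a single gene symbol, also carried signal. Among 13767 such rows 387 were called and changed at least 2-fold for anisomycin against vehicle, 279 for imiquimod against vehicle and 46 for anisomycin against imiquimod.

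Chance was tested by regrouping arrays. For anisomycin against vehicle the real split of the 6 arrays called 9095 genes and the highest of the others 0, for imiquimod against vehicle 8519 and 0, and for anisomycin against imiquimod 4059 and 0. The real split was the 1 of 10 with as many, and 10 splits are too few for a share under 0.05. For genes differing among the 3 groups, 1 of 100 splits of the 9 arrays, the real one, gave as many as 10222 genes, and the highest of the others gave 6502, so chance is unlikely there. That test does not tell which of the groups differ.

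Skeletal muscle genes were lower by the same amount in both treatments, with array medians of 10.0 to 10.7 for vehicle, 8.26 to 8.49 for anisomycin and 7.92 to 8.57 for imiquimod. The tissue lists compared did not fall by the same amount. Muscle and cartilage medians, the furthest apart, lay 1.24 apart with anisomycin (SE 0.27) and 1.116 apart with imiquimod (SE 0.19). This cannot exclude an equal dilution of all resident tissues by infiltrate and thickened epidermis. Cartilage genes were dimmer in vehicle ears, with array medians of 6.88 to 7.23, and falls of dimmer genes may be understated. The SE also treats the genes of a list as independent. A trend with brightness between arrays is argued against by its direction. The 1994 brightest genes shifted upward, by a median of 0.20 with anisomycin and 0.22 with imiquimod, whereas the muscle genes fell. Cyclic loess took the shift with anisomycin from 0.20 to 0.09, and 102% of the median muscle fall with anisomycin and 105% with imiquimod remained. Since removing an upward shift could hardly shrink a fall, these percentages add little. A loss of muscle transcripts under treatment, and more muscle in the pieces of ear taken from vehicle mice, were not tested and may both account for it. The estimated correlation among these genes was 0.884, so the 18 genes count for far fewer independent ones.

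The anisomycin arrays were spread along the difference from imiquimod. Across genes, the difference between anisomycin replicates 1 and 3 correlated with that between replicate 2 and the imiquimod mean at r = 0.589. A brightness trend is argued against, as 101% of this correlation remained after cyclic loess. Different shares of ear tissue stay open. The largest median shift of the muscle, cartilage, adipocyte and hair follicle lists was 0.248 in size, just inside the bound of 0.25 set beforehand against them. The test as run also asked for a margin for the standard error, which was not part of that bound. That margin was not met, so different shares are not excluded. Sebaceous gland genes, which were not in that test, differed by -0.51 between those arrays, which goes with different shares of tissue as much as with a response. Cell cycle genes differed by -0.60. A graded response among the mice was not tested and stays open as well.

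Several antimicrobial and Sprr genes, though not the antimicrobial list as a whole, were lower with anisomycin than with imiquimod, as were 6 of 13 Sprr genes, with 1 higher. Fewer neutrophils with anisomycin could lower S100a8 and S100a9. The 12 neutrophil markers outside the antimicrobial list had a median difference of 0.044 (SE 0.36), with 5 higher and 5 lower, which decides nothing. A different level of Il17a and Il17f transcripts also stays open, since 1 of the 2, Il17f, was lower with anisomycin and Il17a was not called.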

How the results depend on the processing

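Cyclic loess normalization was chosen after seeing the data. The 4 counts of changed genes, the correlation of the treatments' effects, the number of genes shared in direction and the numbers of lists called gave 177 values over all alternatives, and 168 of them stayed within 1.5 times the reported count or, for the correlation, within its jackknife standard error of 0.0328. Some of these values had little or no room to move. That standard error was made from the same leave-one-out correlations that it judges. The variance prior, the centring of arrays and the replicate block left the correlation at 0.8663 by construction. The numbers of lists called under the prior and the array weights repeat the main run, since camera was not given those settings. The exceptions were the count for anisomycin against imiquimod and the number of lists called with camera's estimated correlation. The count was 8557 with array weights and ranged from 2523 to 4766 when 1 array was left out. The number of lists was 0 for anisomycin against vehicle, 2 for imiquimod against vehicle and 0 for anisomycin against imiquimod. The cause of this loss of list calls was not tested, and camera's adjusted p also rose for lists with little estimated correlation. The antimicrobial list, with an estimated correlation of 0.02, went from an adjusted p of 3.53e-08 to 0.0569 for anisomycin against vehicle. Between the treatments the mast cell, basophil and eosinophil list, at -0.015 and so below the preset, went from 0.157 to 0.515. For these lists correlation among the members does not account for the rise alone, so a lost call is not by itself a sign of correlated members. The causes of the changes in the count for anisomycin against imiquimod were not tested. A smaller number of arrays does not account for them alone, since the count was 4493 without anisomycin replicate 3. Of 521 calls of named genes and lists, cyclic loess ended 9, array weights 1 and the trended, robust prior 0, where the weights and the prior could not change the list calls. Leaving out single arrays ended 39 of 457 gene calls and 4 of 64 list calls, the latter being NRF2 targets with anisomycin (adjusted p up to 0.0697), hair follicle markers with anisomycin (0.0509, without vehicle replicate 3), matrix remodelling with imiquimod (0.0595, without vehicle replicate 3) and eicosanoid enzymes between the treatments (0.108, without anisomycin replicate 1). Of the named genes 1 reversed, Rps2 for imiquimod against vehicle, which went from 0.20 to -0.05 after cyclic loess and was no longer called (adjusted p = 0.455), and the cause was not tested. No clear pairing by replicate number was seen, since correlations of same-numbered arrays' deviations ran from -0.201 to 0.196 and no contrast had all 3 above 0.1. This does not exclude a shared order. On the third principal component, with 2.85% of the variance, scores fell from replicate 1 to 3 in both treated groups. They were 4.09, -1.58 and -7.31 for anisomycin and 7.84, 1.26 and -2.32 for imiquimod, but -7.22, 15.5 and -10.3 for vehicle. With the replicate block the counts were 8924, 8280 and 3734 for the 3 contrasts and 10022 among the groups, and not every array correlated best with its own number. Signal over background was not tested, since the table as used here holds no detection values, so whether dim genes such as Il17a were measured above background is open.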

Other observations

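Further gene lists, and single genes within them, gave the following values. Of the interferon gamma and antigen presentation list, 4 MHC class II genes named for their size of change fell with both treatments, H2-Ab1 at -0.998 and -1.03, Cd74 at -0.85 and -0.87, H2-Eb1 at -0.74 and -0.89 and H2-Aa at -0.72 and -0.95 for anisomycin and imiquimod, although the list as a whole was not called, with 3 higher and 7 lower of 22 for anisomycin and 7 and 6 for imiquimod (adjusted p = 0.585 and 0.644). The dendritic and Langerhans cell list was not called against vehicle either (adjusted p = 0.291 and 0.644). Within it the migration-associated genes Ccr7 (1.87 and 0.84) and Fscn1 (2.35 and 1.62) rose and Mgl2 fell (-1.71 and -1.87). Between the treatments 8 of its 17 genes were higher with anisomycin and 1 lower (adjusted p = 0.0137, and adjusted p = 0.515 with an estimated correlation). Nerve and Schwann cell markers fell in 6 of 8 cases with anisomycin and 7 of 8 with imiquimod, with S100b at -1.23 and -1.04 (adjusted p = 0.0204 and 0.000257, and adjusted p = 0.428 and 0.231 with an estimated correlation). The anisomycin call ended with dim genes left out and with arrays centred on stable genes. The exception in that list was the myelin and lymphocyte gene Mal, which rose with anisomycin (1.78) and was at -0.37 and not called with imiquimod, a tested difference of 2.15.

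The basal keratinocyte list showed no common direction, with 5 higher and 5 lower of 13 for anisomycin and 5 and 6 for imiquimod (adjusted p = 0.965 and 0.491), while the stem cell keratin Krt15 fell by 2.46 and 2.54 and the cadherin gene Cdh3 rose by 1.61 and 1.62. For anisomycin this list's median was -0.11 although camera's direction was up. NRF2 and glutathione genes rose in 9 and fell in 4 of 18 with anisomycin and rose in 11 and fell in 2 with imiquimod, with Gsta4 at 4.60 and 4.26 and, with anisomycin, Gstm1 at -2.03 (adjusted p = 0.0473 and 8.13e-05, and adjusted p = 0.345 and 0.143 with an estimated correlation). The anisomycin call ended without anisomycin replicate 2 or vehicle replicate 2, at an adjusted p of up to 0.0697. The mast cell, basophil and eosinophil list was not called, with 4 higher and 6 lower of 16 for anisomycin and 2 and 8 for imiquimod (adjusted p = 0.591 and 0.131). Within it Mrgprb2 fell by 0.85 and 0.91, and the histidine decarboxylase gene Hdc, which neutrophils also express, rose by 3.36 and 3.09. The alpha-beta T and NK cell list was not called, with 8 higher and 4 lower of 20 for anisomycin and 5 and 3 for imiquimod (adjusted p = 0.172 and 0.445). Within it the T-cell receptor complex gene Cd3g fell with both treatments (-1.26 and -1.07), while Il7r (1.05) and Il2ra (1.02) rose with anisomycin. The gamma-delta T cell list, of which 8 of 16 genes were measured, was not called in any contrast (adjusted p = 0.906, 0.627 and 0.297).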
